A study of Mus musculus with 2 samples.

How the data were processed

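Single-cell RNA sequencing was done on 2 pools of mouse somitic gastruloids, 1 untreated and 1 treated with dTAG-13. Gastruloids are aggregates of embryonic stem cells that form embryo-like cell types in culture. Per the labels' protocols, both pools came from an E14 embryonic stem cell line carrying a triple reporter, with an HA-FKBP12F36V tag on the endogenous Zeb2 protein. This tag lets the small molecule dTAG-13 direct the tagged protein to degradation. Aggregates were seeded with 300 sorted cells, received 3 µM CHIR99021 from 48 h and were moved to 10% Matrigel at 96 h. dTAG-13 was given at 100 nM at 72 and 96 h. About 32 gastruloids were pooled per library, live cells were sorted by exclusion of a dead-cell dye, and 10000 cells per library entered the 10x Genomics Chromium 3' v3.1 workflow. The hour of harvest is not given in the sources used here. The sample labels call the control untreated, while the series text names DMSO as the alternative to dTAG-13; it is called untreated here.

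The values deposited by the authors are counts of unique molecular identifiers (UMIs) per gene and cell barcode, whole numbers with no normalization, for 32285 genes. Per the submitters' processing notes these counts were made with Cell Ranger 6.1.2 and the mm10 build. The files hold 7276 barcodes with 158002807 UMIs for the untreated library and 7873 barcodes with 176677276 UMIs for the dTAG-13 library. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes, such as those within a Hox cluster, cannot be fully told apart. Histone genes have near-identical copies, so their counts are uncertain too. Of the gene identifiers, 32235 matched GENCODE release M21 on GRCm38, from which positions were taken.

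Barcodes with fewer than 1000 genes detected or over 10% mitochondrial UMIs were removed, which took 630 untreated and 693 dTAG-13 barcodes. Scrublet, run within scanpy 1.11.5, marked 1 untreated and 0 dTAG-13 barcodes as doublets by its automatic threshold, which is too few to be credible. The barcodes with the highest scores were therefore removed, at 0.8% per 1000 barcodes. These were 424 untreated and 496 dTAG-13 barcodes, of which 415 and 492 had passed the other filters. This left 6231 untreated and 6688 dTAG-13 cells. Kept cells had a median of 20073 and 20207 UMIs.

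Counts were scaled to 10000 per cell and log transformed. Both libraries were clustered jointly without batch integration, on 2000 highly variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2). A cluster was given the name of a cell type, with the ending "-like", from 19 marker lists. The score was the log2 ratio of a marker's CPM in the cluster over all other cells, with a prior of 5 CPM. The name needed a mean of at least 1.0 over the markers, at least 3 markers detected in 10% of cells with a log2 ratio of at least 1.0, and no other type with more markers among the 10 leading genes. Clusters of very low UMI counts needed a marker among these as well. The scoring thresholds were settled after a first rule had named clusters on weak grounds, so which clusters are left unnamed, with numbers, depends on a choice made after the data were seen. The first rule would have named clusters 0 and 15 pluripotent and cluster 8 surface ectoderm. Unnamed clusters sharing at least 5 of their 10 leading genes were joined. Of 16 clusters, 9 were named.

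With 1 library per group there is no replicate, and no test between groups was made. Intervals are 95% exact Clopper-Pearson (shares) or Poisson (summed counts) intervals, and cover counting error only. UMIs were summed over all kept cells of a library, and over each of the 10 classes with at least 100 cells in both libraries, and scaled to a common total (CPM). Ratios are log2 of dTAG-13 over untreated with a prior of 1 CPM. The interval of a ratio is the exact conditional interval of the 2 counts without the prior, so at low CPM it can lie farther from 0 than the printed ratio, as for Dlx3 in the whole library (ratio 1.4, interval 1.73 to 2.21) or Pax6 (-0.95, -1.56 to -1.12). A gene list was described by its median log2 ratio over members with at least 10 UMIs, where at least 5 were measured. This median was set against 10000 random lists of the same size matched on mean expression. A list is called above or below the random range when its percentile was over 97.5 or under 2.5, which describes these libraries and is not a test of the treatment. Apart from the 19 marker lists, 19 lists of pathways and gene families were used. Within a class, the markers of that class were left out. The genes named are the 12 highest and 12 lowest of the whole library among those with at least 20 CPM in 1 library. Within a class they are the 8 highest and 8 lowest with at least 50 UMIs in addition, leaving out the markers of the class. Predicted genes were counted and not named. From each list up to 4 members with the largest ratios were named, and Zeb2 and Zeb1 were always reported. The lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the naming rule, the size limit for counting members (1.5-fold) and 4 alternatives added later.

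The part of a ratio that cell shares account for was computed by giving both libraries the mean class profile and leaving each its own UMI share per class. The part within classes was computed with mean shares and each library's own profiles. For values per cell, each cell was thinned to 5000 UMIs, which left out 87 untreated and 81 dTAG-13 cells. Phases were assigned with scanpy's cell-cycle scores.

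Alternatives covered the cell filter, doublet removal, the number of variable genes, the resolution, clustering of each library alone, projection of dTAG-13 cells onto the untreated cells, and clustering without genes at an absolute log2 ratio of 1 or more. For ratios they covered edgeR 4.0.16 TMM scaling, DESeq2 1.42.0 size factors, the mean of per-cell CPM, thinning and a prior of 5 CPM. Named genes within classes were also scored without the 5 cells with most UMIs of the gene in each library. Unnamed clusters in an alternative were given the class that most of their cells had. Where the cell filter or doublet removal changed, cells were clustered and named again, so a class can then hold other cells. The code was tested on simulated data. In simulated whole libraries, 100% of 95 genes changed 2-fold were recovered among 16120 genes. In simulated classes of 100 cells per library, 90.41% of 73 such genes were recovered among 7475 genes. Intervals covered the true ratio for 95.46% and 95.73% of genes. Of 200 unchanged lists, 4% lay outside the random range. The simulated counts were independent Poisson draws, and the unchanged lists were random genes. These rates therefore check the code, and not the variation between real cells or between genes that vary together.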

Results

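Somitic gastruloids with a degradable Zeb2 protein were profiled by single-cell RNA sequencing without treatment and after dTAG-13 at 72 and 96 h. The comparison asks how the cell types of gastruloids and their expression differ when Zeb2 is degraded. Zeb2 is a zinc-finger repressor known for its part in epithelial-to-mesenchymal transition and neural development. There was 1 library per group, so no difference below has a replicate check. Kept cells numbered 6231 in the untreated library and 6688 in the dTAG-13 library, with 140019633 and 151601709 UMIs.

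The Zeb2 transcript (ENSMUSG00000026872, chromosome 2, 44983632 to 45117395, minus strand, GRCm38) was present in both libraries. It stood at 67.9 CPM (95% Poisson interval 66.5 to 69.3) in the untreated library and 94.6 CPM (93.0 to 96.1) in the dTAG-13 library, a log2 ratio of 0.47. dTAG-13 acts on the protein, so the transcript level does not check the labels. Zeb2 was higher in the dTAG-13 library in 8 of the 10 classes with enough cells. In spinal cord-like cells it was 108 CPM (96.1 to 121) against 218 CPM (204 to 234), in presomitic mesoderm-like cells 85.5 CPM (81.1 to 90.2) against 152 CPM (144 to 159), and in cluster 0 71.4 CPM (64.8 to 78.4) against 125 CPM (121 to 129). Pluripotent-like cells held 2.0 CPM (1.28 to 2.97) against 2.22 CPM (1.55 to 3.09), and endoderm-like cells 9.71 CPM (6.60 to 13.8) against 10.3 CPM (7.84 to 13.2), so no difference was detectable there. Without doublet removal the log2 ratio in endoderm-like cells was 0.89 instead of 0.07, and that in somite-like cells 0.23 instead of 0.41. In that setting all cells were clustered and named again, so the classes differ too. The somite-like class then held 15.4% of untreated and 11.3% of dTAG-13 cells, instead of 10.9% and 7.31%. Thinned to 5000 UMIs, that in clusters 1+8 was 0.22 instead of 0.55. Zeb1, the other member of the family (chromosome 18, 5591860 to 5775467, plus strand), was lower in the whole dTAG-13 library, at 20.1 against 31.4 CPM (log2 ratio -0.62). Within classes Zeb1 went both ways, from -1.0 in cluster 0 to 0.30 in presomitic mesoderm-like cells.

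**Figure D1:**
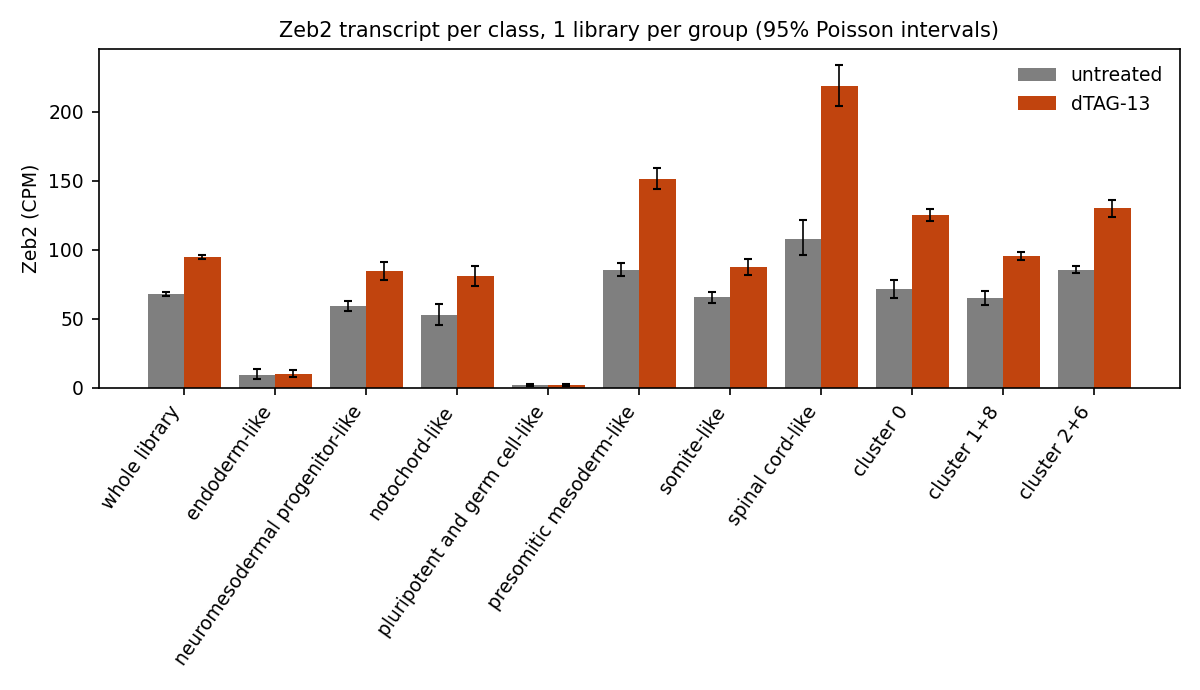
Zeb2 transcript level in CPM (vertical axis) in the whole library and in each class, with grey bars for the untreated and orange bars for the dTAG-13 library; error bars are 95% Poisson intervals. Zeb2 was near 2 CPM in pluripotent-like cells of both libraries and reached 218 CPM in spinal cord-like cells of the dTAG-13 library.

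After thinning each cell to 5000 UMIs, Zeb2 was detected in 35.6% of untreated (95% binomial interval 27.9 to 43.8) and 63.9% of dTAG-13 (56.8 to 70.5) spinal cord-like cells. In presomitic mesoderm-like cells the shares were 35.6% (32.2 to 39.1) and 50.1% (45.5 to 54.7). Of the 8 classes with higher Zeb2, the intervals of this share lay apart in 5 and overlapped in 3. The overlapping ones were clusters 1+8, at 29.6% (25.5 to 34.0) and 31.0% (28.9 to 33.1), notochord-like cells, at 25.3% (19.8 to 31.5) and 31.1% (26.5 to 36.1), and somite-like cells, at 29.2% (25.8 to 32.8) and 36.6% (32.3 to 41.1). Pluripotent-like cells, which serve as background, gave 1.62% and 1.45%, with median depths before thinning of 26434 and 27062.5 UMIs. The spinal cord-like cells had median depths of 17681 and 18237.5 UMIs. Without thinning, the spinal cord-like shares were 77.2% and 94.1%, and the pluripotent-like shares 5.02% and 5.05%.

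Over whole libraries, genes of epithelial junctions and keratins were higher in the dTAG-13 library. The largest ratio was that of Cldn7, a tight-junction protein, at 19.0 against 101 CPM (log2 ratio 2.35). It was followed by the small GTPase Rab25 (2.28), the homeobox gene Dlx5 (2.12), the uroplakin Upk1a (1.79) and the epithelial 14-3-3 protein Sfn (1.77). The junction and polarity genes Cldn3 (1.69), Crb3 (1.61) and Cldn6 (1.49), the splicing regulator Esrp1 (1.52) and the keratins Krt18 (1.52) and Krt8 (1.50) came next. The kinase gene Pim2 closed the 12 highest, at 12.6 against 36.3 CPM (1.45). Cldn7 lies on chromosome 11 at 69964779 to 69967885, and Krt8 and Krt18 neighbour each other on chromosome 15, at 101996698 to 102004482 and 102028180 to 102032027.

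Genes of the Notch pathway and Hox and Cdx genes of axial identity were lower in the dTAG-13 library. Hes5, a Notch target of neural progenitors (chromosome 4, 154960923 to 154962371), stood at 47.1 CPM untreated (95% Poisson interval 46.0 to 48.3) and 12.9 CPM with dTAG-13 (12.4 to 13.5), a log2 ratio of -1.79. The Notch ligand Dll1 (-1.22), the segmentation clock gene Hes7 (-1.15), the caudal homeobox gene Cdx4 (-1.25) and the hedgehog co-receptor Gas1 (-1.05) were also among the 12 lowest. Hoxd4 (-1.34), Hoxa9 (-1.27), Hoxc6 (-1.17), Hoxc4 (-1.07), Hoxc8 (-1.02) and the antisense RNA Hoxb5os (-1.45) were lower as well. The histone gene Hist1h2ap (-1.16) completed the list. Among the 12 lowest ratios before naming were 2 predicted genes, which were passed over. The median of all genes with at least 10 UMIs was 0.02.

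**Figure D2:**
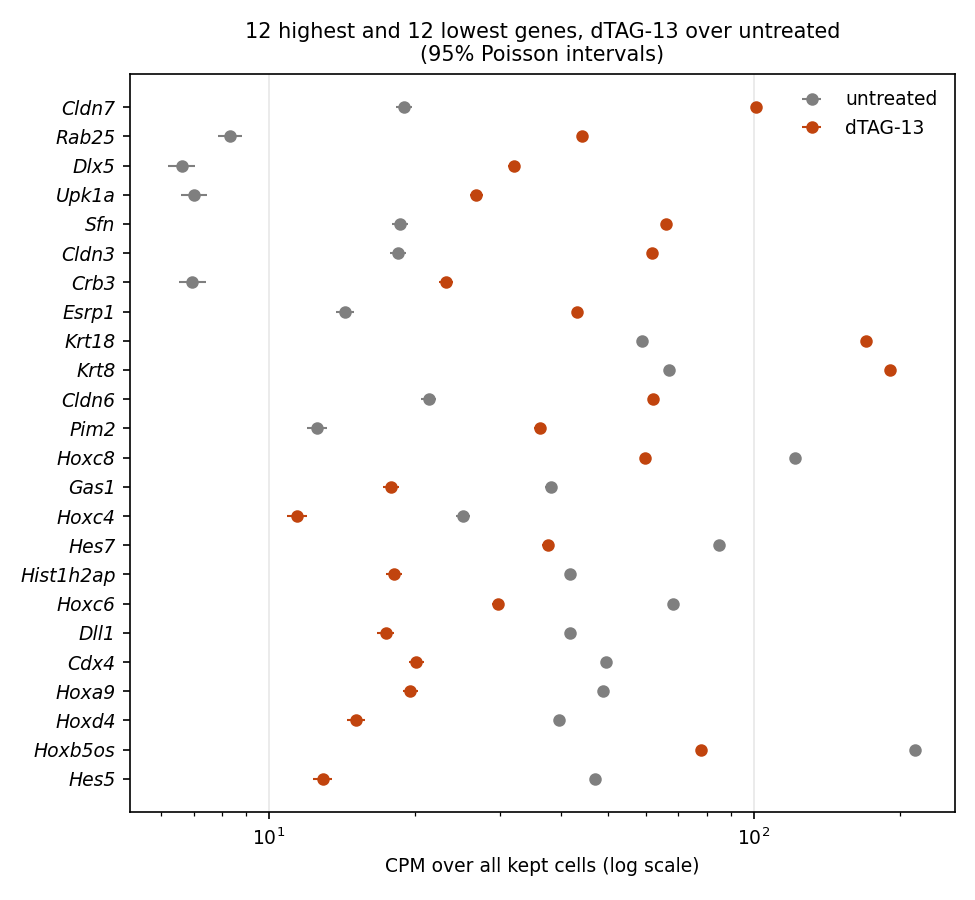
CPM over all kept cells (horizontal log axis) of the 12 genes with the highest and the 12 with the lowest ratio of dTAG-13 over untreated, ordered by ratio; grey points are the untreated and orange points the dTAG-13 library, with 95% Poisson intervals where these are wider than the point. Cldn7 differed from 19.0 to 101 CPM and Hes5 from 47.1 to 12.9 CPM.

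Of the 38 lists scored on whole libraries, 10 lay above the range of matched random lists, 16 below and 12 within it. The epithelial list was highest: its median log2 ratio was 1.22, and 25 of 29 genes were at least 1.5-fold higher and 0 lower. Beyond the genes above it holds Ap1m2 (2.07), Epcam (1.28) and the adhesion gene Cdh1, at 18.8 against 47.4 CPM (1.29). Endoderm markers followed with a median of 0.94 and 10 of 16 higher; 7 of their listed genes, such as Cldn7 and Krt18, are also in the epithelial list. Surface ectoderm markers had a median of 0.55 (5 of 10 higher, among them Dlx3 at 1.4 and Grhl3 at 1.0). Pluripotent and germ cell markers had a median of 0.47 (5 of 16 higher, with Tfap2c at 1.05 and Pou5f1 at 0.75). Smaller medians above the range were those of epiblast and primitive streak markers (0.18, Fgf5 1.05), neural crest markers (0.16, Dlx5 2.12) and neuron markers (0.13, Stmn2 0.75). With a prior of 5 CPM the percentiles of the neuron (95.8) and neural crest (94.2) markers fell within the range, as did that of the epiblast markers with DESeq2 size factors (97.2).

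Several lists of mesodermal, spinal cord and axial genes lay below. Presomitic mesoderm markers had a median of -0.68 (8 of 12 at least 1.5-fold lower, with Tbx6 at -1.44) and somite markers a median of -0.68 (7 of 11 lower, with Tcf15 at -0.72). Neuromesodermal progenitor markers had a median of -0.48 (5 of 12 lower, with Wnt3a at -1.23 and Cdx2 at -0.61) and spinal cord markers one of -0.22 (4 of 15 lower, with Pax6 at -0.95). Intermediate mesoderm markers (-0.30) and dermomyotome and myotome markers (-0.06) were below the range too, the latter by a margin that edgeR TMM scaling removed (percentile 4.04). Hox groups 1 to 4 had a median of -0.81 with 10 of 12 lower, Hox groups 5 to 9 one of -0.69 with 9 of 15 lower, and Hox groups 10 to 13, at a median level of 0.244 CPM, one of -0.15. The sclerotome (-0.04), endothelium (-0.02), blood (0.02), notochord (0.14), cardiac (0.12), lateral plate and allantois (0.08) and extraembryonic (0.01) markers lay within the range.

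Among the pathway lists, Notch and segmentation clock genes had a median of -0.40 (8 of 20 lower), FGF and ERK response genes -0.30 (Fgfbp3 -0.82), canonical WNT response genes -0.27 (Wnt5b -0.69, and Rnf43 the other way at 0.60) and the ZEB and SNAIL family -0.42 (Snai1 -0.67). The mesenchymal list had a median of -0.20, with Vim at 153 against 93.3 CPM (-0.71) and Cdh2 at 87.9 against 55.5 CPM (-0.65). Somite extracellular matrix and adhesion genes (-0.20) and the integrated stress response (-0.09) were also below. BMP and SMAD response genes (0.22, Msx1 0.51 and Id3 0.47), hypoxia and glycolysis genes (0.22, Slc2a3 0.71 and Gapdh 0.61) and G2 and M phase genes (0.07) were above. The retinoic acid pathway (-0.04, with Crabp2 at -0.96), S phase (-0.03), p53 response (-0.04), dissociation and immediate early (0.12) and mitochondrial (0.01) lists lay within the range.

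Cells of the 2 libraries fell into 16 clusters, each with cells of both. Cluster 0 was led by Pim2, Pou3f1, Calca and Wnt8a and expressed the pluripotency gene Pou5f1 at 198 CPM and Epcam at 710 CPM. Clusters 1 and 8 were led by Sfn, Upk1a, Dlx5, Ppl and Grhl3. Clusters 2 and 6 were led by Hoxa9, Hoxc9 and Hoxc6, with Sox2 at 187 CPM in both. None of these met the rule for a name. The named clusters were presomitic mesoderm-like, neuromesodermal progenitor-like, somite-like, pluripotent-like (listed as pluripotent and germ cell), notochord-like, endoderm-like, spinal cord-like, epiblast-like (epiblast and primitive streak) and endothelium-like, 1 cluster each.

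The libraries held these clusters in different shares. Clusters 2+6 made up 32.1% of untreated cells (95% binomial interval 31.0 to 33.3) and 8.49% of dTAG-13 cells (7.84 to 9.19). Clusters 1+8 made up 7.45% (6.81 to 8.13) and 28.2% (27.1 to 29.3), and cluster 0 4.83% (4.31 to 5.39) and 19.8% (18.8 to 20.7). Neuromesodermal progenitor-like cells were 13.4% (12.6 to 14.3) and 5.53% (5.00 to 6.11), presomitic mesoderm-like cells 12.7% (11.9 to 13.6) and 7.03% (6.43 to 7.67), and somite-like cells 10.9% (10.1 to 11.7) and 7.31% (6.70 to 7.96). Notochord-like cells were 3.68% and 5.68%, endoderm-like cells 2.52% and 3.90%, pluripotent-like cells 7.03% and 8.28%, and spinal cord-like cells 2.39% and 3.05%. With at least 2500 genes detected, the differences of neuromesodermal progenitor-like cells and clusters 2+6 were -18.1 and -13.8 points instead of -7.87 and -23.6. With each library clustered alone, the pluripotent-like difference was 2.53 instead of 1.25 points. No untreated cluster then matched endoderm-like or spinal cord-like cells, and no dTAG-13 cluster matched epiblast-like cells. Their differences of 3.93, 3.24 and -4.40 points, instead of 1.38, 0.659 and -0.380, therefore compare with 0. The endothelium-like difference turned from -0.209 to 1.17 points in that setting. The epiblast-like (1.85% and 1.47%) and endothelium-like (0.658% and 0.449%) shares had overlapping intervals. The intervals of the pluripotent-like and spinal cord-like shares also overlapped. Cluster 14, with a median of 2732 UMIs, held 26 and 19 cells, and cluster 15, with a median of 93677.5 UMIs, held 2 and 40.

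Several genes that lead clusters 0, 1+8 and 2+6 are among those that differ most between the libraries. Clustered without the genes at an absolute log2 ratio of 1 or more, the cells matched to clusters 2+6 made up 38.1% and 19.4%, those matched to clusters 1+8 4.16% and 17.5%, and those matched to cluster 0 5.20% and 20.4%. Projected onto the untreated cells alone, 14.1% of dTAG-13 cells were nearest to clusters 2+6, 24.1% to clusters 1+8 and 18.7% to cluster 0. These clusters were each mostly of 1 library, with 301 untreated and 1321 dTAG-13 cells in cluster 0, 464 and 1884 in clusters 1+8, and 2001 and 568 in clusters 2+6. The live-cell sort stands before all shares.

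**Figure D3:**
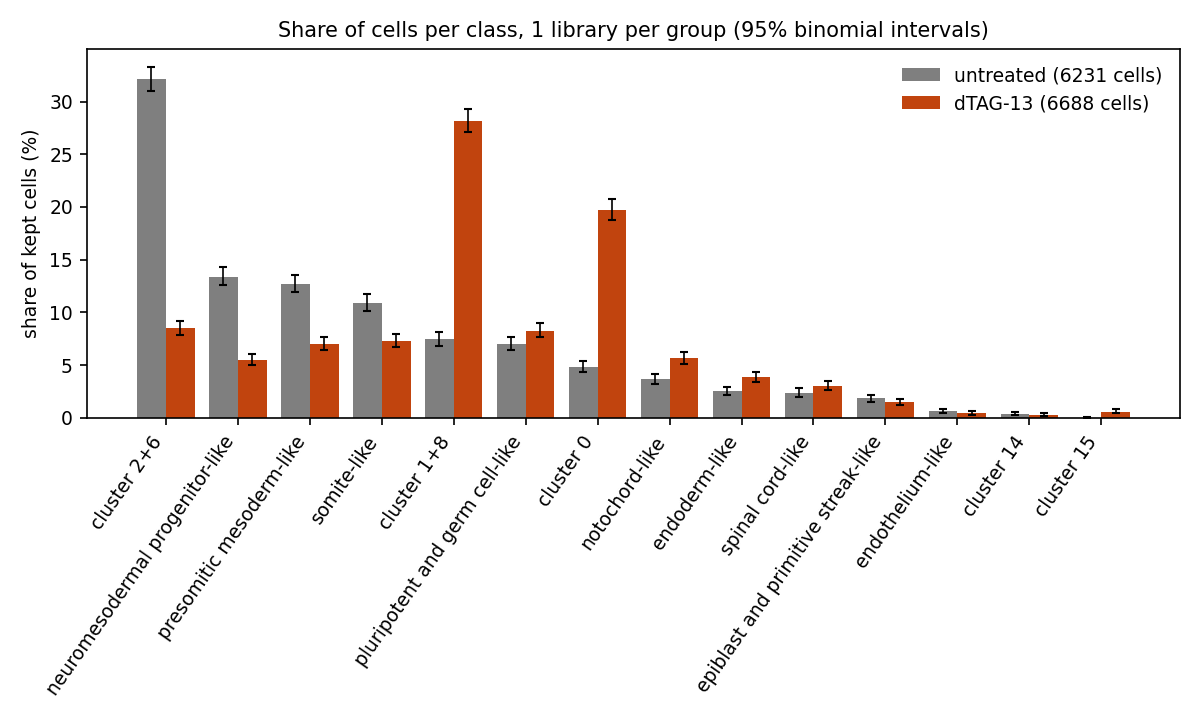
Share of kept cells in percent (vertical axis) in each class, ordered by the untreated share, with grey bars for the untreated and orange bars for the dTAG-13 library; error bars are 95% exact binomial intervals. Clusters 2+6 were 32.1% and 8.49%, and clusters 1+8 were 7.45% and 28.2%.

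Cell shares and expression within classes were then separated. With mean class profiles and each library's own shares, the epithelial list had a median of 0.75; with mean shares and each library's own profiles, it had a median of 0.43. For presomitic mesoderm markers the values were -0.48 and -0.23, for somite markers -0.39 and -0.16, and for Hox groups 5 to 9 -0.57 and -0.09. Spinal cord markers had a share part of -0.04 and a part within classes of -0.22. For the BMP and SMAD response the share part was -0.04 and the part within classes 0.23. Single genes divided in the same way, but Sfn (1.55 from shares and 0.14 within classes) and Pim2 (1.38 and 0.06) lead clusters 1+8 and 0, so that their place among shares follows in part from the clustering. The same holds for the epithelial, presomitic mesoderm, somite and Hox 5 to 9 lists, members of which lead or name classes. The genes Hist1h2ap (-0.08 and -1.09) and Zeb2 (-0.15 and 0.62) differed within classes. Cldn7 (1.00 and 1.24) and Hes5 (-0.68 and -1.11) held both parts.

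Within classes, the epithelial list lay above the random range in 9 of 10 classes. Its median was 1.16 in spinal cord-like cells (17 of 22 genes at least 1.5-fold higher), 1.04 in neuromesodermal progenitor-like cells (20 of 28), 0.81 in clusters 2+6 (18 of 28), 0.43 in somite-like, 0.41 in notochord-like, 0.28 in presomitic mesoderm-like and 0.17 in endoderm-like cells. In pluripotent-like cells it was 0.05, within the range, and Cdh1 was 43.2 CPM untreated and 43.3 CPM with dTAG-13. Cldn7 was 9.97 against 62.0 CPM in spinal cord-like cells (log2 ratio 2.52, 95% interval 2.06 to 3.27), 12.8 against 73.7 CPM in neuromesodermal progenitor-like cells and 6.39 against 40.3 CPM in clusters 2+6. In somite-like cells the list was at a median level of 2.53 CPM, with Krt8 at 14 against 33.5 CPM and Krt18 at 9.43 against 24.0 CPM. In presomitic mesoderm-like cells the list was at a median level of 2.97 CPM, and once cells were thinned to 5000 UMIs its percentile was 39.1, and that of endoderm-like cells 88.1, both within the range. In cluster 0 (0.48) and clusters 1+8 (0.49) the list overlaps the genes that set the clusters.

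The BMP and SMAD response list also lay above the range in 9 of 10 classes, with a median of 0.73 in neuromesodermal progenitor-like cells (9 of 16 higher), 0.62 in spinal cord-like cells (7 of 14), 0.61 in clusters 2+6 (9 of 15), 0.39 in presomitic mesoderm-like and 0.37 in somite-like cells. Pluripotent-like cells gave -0.13, within the range. Id1, an inhibitor of basic helix-loop-helix factors and a direct BMP target, was 102 against 229 CPM in neuromesodermal progenitor-like cells (1.16), 92.5 against 172 CPM in clusters 2+6 (0.89) and 105 against 162 CPM in somite-like cells (0.62). In clusters 1+8 Id1 went the other way, at 93.8 against 76.6 CPM (-0.29, 95% interval -0.40 to -0.18), and in cluster 0 it was at 0.06 (-0.06 to 0.18), although the list was above the range in both. Id2 was 34.9 against 99.8 CPM in presomitic mesoderm-like cells (1.49). In cluster 0 (0.16) the list fell within the range without doublet removal (percentile 91.2).

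In neuromesodermal progenitor-like cells, where the epithelial and BMP medians were among the largest, 2 lists that read cell handling and quality were above the range too. These were dissociation and immediate early genes (0.38) and mitochondrial transcripts (0.08, percentile 98.5), the latter within the range in the other 9 classes. The dissociation list was within the range in spinal cord-like cells (0.04) and clusters 2+6 (-0.07). It was below the range in cluster 0 (-0.40), somite-like (-0.23), endoderm-like (-0.19) and presomitic mesoderm-like cells (-0.17), but within it in all 4 after thinning (percentiles 20.98, 32.2, 80.96 and 87.6).

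Hox groups 5 to 9, which mark trunk levels of the axis, had a median of -1.31 in spinal cord-like cells (8 of 9 at least 1.5-fold lower), -0.92 in presomitic mesoderm-like cells (10 of 15) and -0.82 in somite-like cells (12 of 14). In neuromesodermal progenitor-like cells the median was -0.07, within the range, and in clusters 2+6 it was 0.13, above it. Members of this list, such as Hoxa9, Hoxc9 and Hoxc6, lead clusters 2+6, so the value there depends in part on the clustering. Projected onto the untreated cells, clusters 2+6 turned to a percentile of 9.39 and neuromesodermal progenitor-like cells to 0.15. Hoxc8 was 56.8 against 19.5 CPM in presomitic mesoderm-like cells (-1.49) and 17.6 against 6.38 CPM in somite-like cells (-1.33). In pluripotent-like cells the list was at a median level of 1.54 CPM, and Hoxc8 and Hoxa9 were under 2.4% of their whole-library CPM, near background. In endoderm-like cells the list was below the range (-0.54), but above it without doublet removal (percentile 100). Hox groups 1 to 4 lay below the range in 9 of 10 classes, with a median of -1.02 in spinal cord-like cells. Of these calls, those of endoderm-like (percentile 69.4) and notochord-like cells (5.03) ended without doublet removal, and that of cluster 0 ended after thinning (4.97). In presomitic mesoderm-like cells the median was -0.08, within the range, but below it with DESeq2 size factors (percentile 2.49), cells averaged (2.15) or a prior of 5 CPM (1.9). The median of Notch and segmentation clock genes lay below the range in 7 classes. It was -0.52 in endoderm-like (7 of 15 genes at least 1.5-fold lower), -0.43 in neuromesodermal progenitor-like (8 of 17), -0.39 in somite-like (5 of 19), -0.29 in cluster 1+8 (2 of 16) and -0.21 in notochord-like cells (3 of 15). The presomitic mesoderm-like (-0.13, 2 of 10) and cluster 2+6 (-0.15, 1 of 17) medians were within the range when cells were averaged (percentiles 7.6 and 57.3). The somite-like median fell within it after thinning (3.62), and the notochord-like one with projected classes (2.505).

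**Figure D4:**
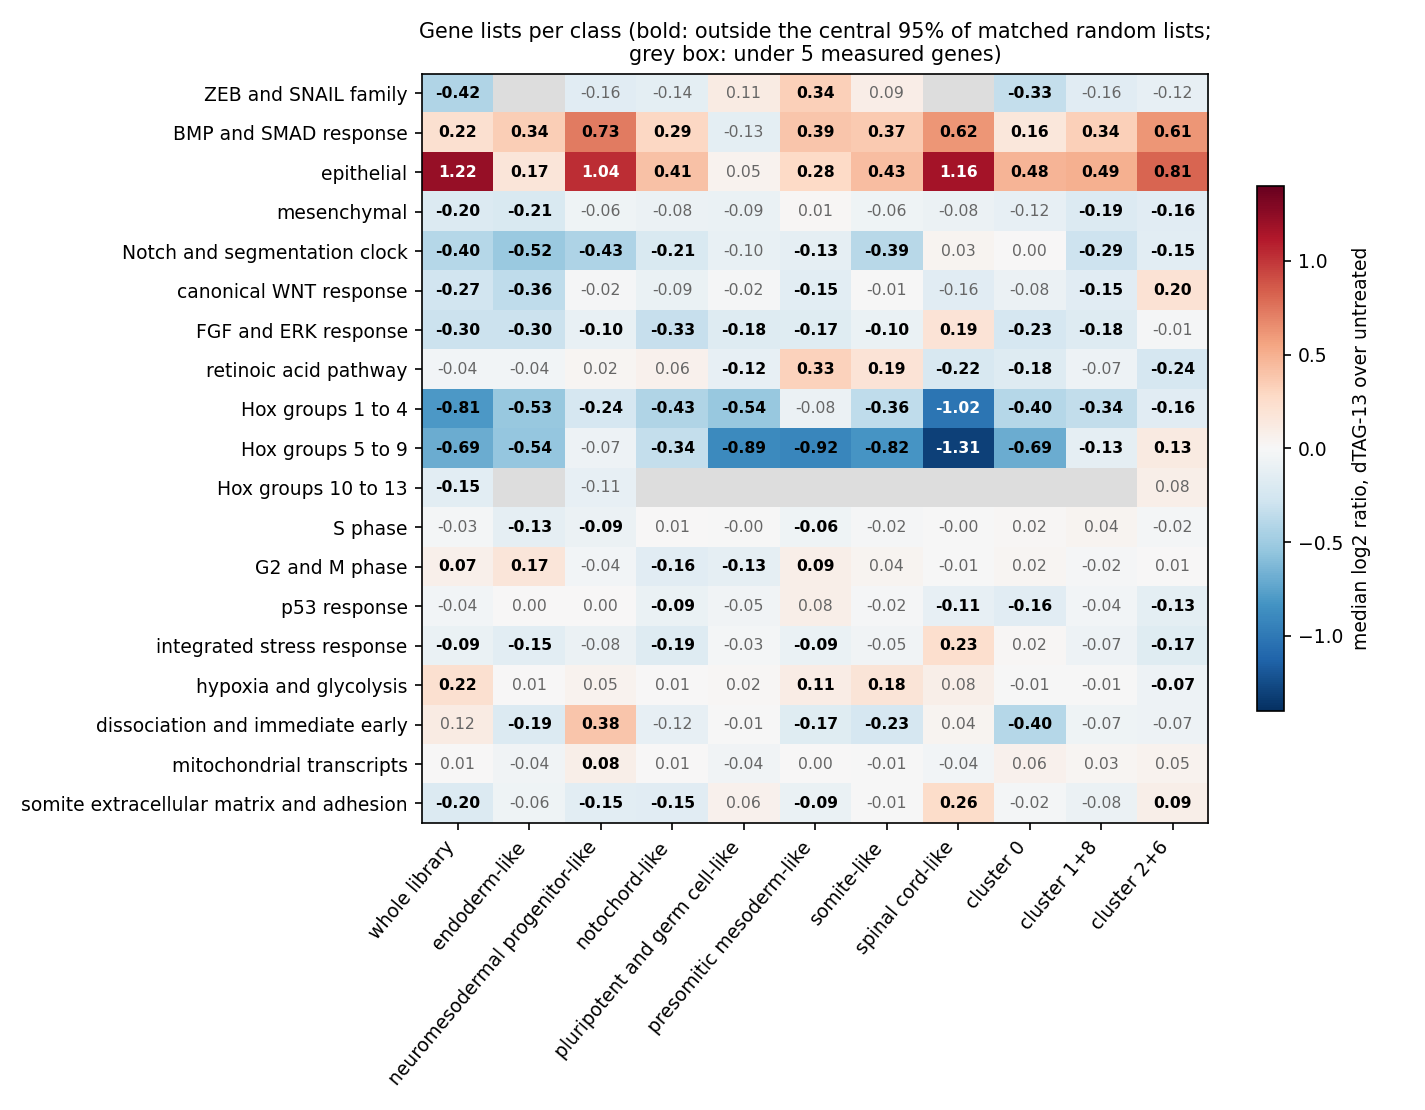
Median log2 ratio of dTAG-13 over untreated for 19 gene lists (rows) in the whole library and 10 classes (columns), from blue for lower to red for higher; bold values lie outside the central 95% of matched random lists, and grey boxes have under 5 measured genes. The epithelial list reaches 1.16 in spinal cord-like cells and stands at 0.05 in pluripotent-like cells.

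In neuromesodermal progenitor-like cells, which can form both neural tube and paraxial mesoderm, the highest genes were the glutathione peroxidase Gpx2 (2.63 against 23.0 CPM, log2 ratio 2.73, 95% interval 2.65 to 3.64), Cldn7 (2.43), Dlx5 (2.03), Rab25 (1.90), the actin bundler Espn (1.63), AY761185 (1.46) and Alox15 (1.46). Sprr2a3 (1.91) leads the cluster itself and is not read as a result. AY761185 is a leading gene of the notochord-like cluster, and whether notochord-like cells were among these cells was not tested. The lowest were Hes5 (91.2 against 31.8 CPM, -1.49), Hist1h2ap (-1.06), Mex3b (-1.0), the retinoic acid binding protein Crabp2 (-0.91), Rtn1 (-0.81), Dll3 (-0.77), Tbx6 (-0.77) and the Notch feedback gene Nrarp (-0.73).

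In presomitic mesoderm-like cells, the precursors of somites, the LIM homeobox gene Lhx1 was highest at 36.4 against 108 CPM (1.54, 95% interval 1.42 to 1.71). Id2 (1.49), Samd3 (1.25), the homeobox gene Msx1 (1.17), Scml2 (1.13), Arl4a (1.12), the desmosomal cadherin Dsg2 (1.10) and Car2 (1.07) followed. Cdx4 was lowest at 23.7 against 5.25 CPM (-1.99), followed by Hoxc8 (-1.49), Hoxc9 (-1.42), Hoxc6 (-1.34), Fgf17 (-1.31), Hist1h2ap (-1.26), Acot7 (-1.15) and Hoxb9 (-1.09). In the dTAG-13 library 5 cells held 71.7% of the Cdx4 UMIs, and without the top 5 cells of each library its ratio was -2.92. The retinoic acid pathway list was above the range (0.33, with Meis2 at 202 against 330 CPM). In somite-like cells, Gata6 (1.30), Krt18 (1.26), Sdc4 (1.21), Krt8 (1.21), Lefty1 (1.03), Etv2 (1.02), Espn (1.01) and Elmo1 (1.00) were highest. Etv2 turned to -0.41 without the 5 cells with most of its UMIs in each library, which held 80.9% of them in the dTAG-13 library. Cdx2 (24.7 against 8.22 CPM, -1.48), Pcp4 (-1.46), Hoxb9 (-1.22), Hoxaas3 (-1.11), Dmrt2 (-1.05), Hist1h2ap (-1.04), Hoxb5os (-1.02) and Phlda1 (-1.02) were lowest.

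In spinal cord-like cells the highest genes were Cldn7, Krt8 (1.71), Tfap2c (1.67), Car2 (1.55), Krt18 (1.39), Espn (1.34), Arhgap29 (1.33) and Gprc5c (1.32). The lowest was Lefty1, an inhibitor of Nodal signalling, at 54.6 against 1.79 CPM (-4.32, 95% interval -6.27 to -3.86); 5 of the 149 untreated cells held 70.3% of its UMIs. Wnt4 (-1.53), Hoxb8 (-1.44), the WNT receptor Fzd10 (-1.35), Hoxb4 (-1.33), Cdx2 (-1.31), Hoxb7 (-1.31) and Hoxb2 (-1.17) followed. In clusters 2+6 the highest genes were Cldn7 (2.48), Cldn6 (1.58), Krt8 (1.29), Esrp1 (1.24), Mapk13 (1.07), Epcam (132 against 271 CPM, 1.04), Sct (1.04) and Pla2g7 (1.03). Lefty1 (-1.80), Rfx4 (-1.47), Hist1h2ap (-1.12), the retinoic acid binding protein Crabp1 (-0.97), Gas1 (-0.94) and Irx5 (-0.86) were lowest, beside Fgfbp3 (-1.17) and Hes5 (-1.09), which lead these clusters. Lefty1 was at -2.68 without the top 5 cells of each library.

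In notochord-like cells Car3 (1.60), Ppp4r4 (1.57), the WNT inhibitor Dkk1 (1.42), Efemp1 (1.29), Pifo (1.22), Cldn7 (1.10) and Sprr2a3 (1.07) were highest, beside Pgam2 (1.13), which leads the cluster. Without the top 5 cells of each library, Pifo was at 1.82. The imprinted gene Phlda2 was lowest, at 107 against 27.8 CPM (-1.91), followed by Vtn (-1.51), Dand5 (-1.18), Tnnt3 (-1.13), Ppp1r1a (-1.12), Hist1h2ap (-1.08), Tcf15 (-1.07) and Hoxb2 (-1.04). Of the 229 untreated cells, 5 held 56.4% of the Phlda2 UMIs. Without the top 5 cells of each library Phlda2 was at -1.38 and Vtn at -1.58. In endoderm-like cells Sfn (1.56), the imprinted RNA H19 (127 against 308 CPM, 1.27), Fgfbp1 (1.10), Id1 (1.07), Ypel2 (0.98), Cep170b (0.89), Phpt1 (0.82) and Pttg1 (0.82) were highest. Thinned to 5000 UMIs, Fgfbp1 turned to -0.43, and without the 5 cells with most of its UMIs in each library it was 2.64. Ina (-1.36), Rspo3 (-1.31), Hist1h2ap (-1.26), Vim (-1.11), Vtn (-1.07), Pip4k2b (-0.96), Hist1h1b (-0.93) and Hist1h2ae (-0.93) were lowest.

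Ratios in pluripotent-like cells were smaller. The highest were Fabp3 (81.9 against 155 CPM, 0.91), Fthl17c (0.74), Ndufa4l2 (0.72), Rhox6 (0.71), Ifi27 (0.63), AU020206 (0.59), Lgals3 (0.58) and Nphs1 (0.58). The lowest were Hist1h2ap (-0.96), Peg10 (-0.74), Hist1h2ae (-0.71), Trh (-0.71), Rps6ka6 (-0.64), Rnft1 (-0.58), Rps27 (-0.54) and Prtg (-0.53). In cluster 0, Krt7 (1.98), Crb3 (1.14), Cldn7 (1.08), Eras (1.01), Krt8 (1.01), Ap1m2 (0.96), Krt18 (0.94) and Rab25 (0.85) were highest. The Nodal inhibitors Lefty2 (54.0 against 9.62 CPM, -2.37) and Lefty1 (178 against 62.4 CPM, -1.50) were among the lowest, with Morc1 (-2.24), Fabp7 (-1.55), Tcf15 (-1.42), Dppa5a (-1.39), the Nodal co-receptor Tdgf1 (-1.36) and Dnah8 (-1.27). Of the 301 untreated cells, 5 held 48.9% of the Lefty1, 39.7% of the Lefty2 and 54.5% of the Tdgf1 UMIs. Without the top 5 cells of each library the ratios were -0.82 for Lefty1, -2.19 for Lefty2 and -0.76 for Tdgf1. For Morc1 the top 5 untreated cells held 43.0%, and its ratio without the top 5 of each library was -1.84. Morc1 and Dppa5a are leading genes of the pluripotent-like cluster, and Tdgf1 is one of its naming markers. Whether cluster 0 held different amounts of such cells or their RNA was not tested. In clusters 1+8 the iron exporter Slc40a1 (2.04), Cldn7 (1.33), Crb3 (1.15), Gstm1 (1.10) and Grhl2 (1.09) were highest, beside Trim29 (1.56), Rab25 (1.45) and Wnt4 (1.28), which lead these clusters. Hes5 (-1.43), Hoxd4 (-1.20), Fgfbp3 (-1.0), Lefty1 (-0.99), Fst (-0.93), Hist1h2ap (-0.91), Rasgrp2 (-0.86) and Dppa5a (-0.80) were lowest. Without the top 5 cells of each library, Fst was at -0.50. The limit given for Dppa5a in cluster 0 holds here too.

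At 5000 UMIs per cell, the median number of genes was 2078 in untreated and 2099 in dTAG-13 cells, and without thinning 4555 and 4635. S phase was assigned to 40.1% of untreated (38.8 to 41.3) and 35.6% of dTAG-13 cells (34.5 to 36.8), G2 and M phase to 55.5% and 57.5%, and G1 to 4.44% and 6.84%. Without thinning the S phase shares were 41.9% and 37.6%. Thinned to 2500 UMIs, the G1 shares were 9.16% (8.45 to 9.91) and 10.5% (9.76 to 11.2), with overlapping intervals. The phase calls also read free RNA and cell type, and no rate of cycling is taken from them.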

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

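The difference between classes was not tested for any list here, and no pattern was weighed. Each list lay above the range of matched random lists in at least 1 class and below it in at least 1. It is given for the class with the highest and the one with the lowest such median log2 ratio of dTAG-13 over untreated, picked after the values were seen, so most lists were less evenly split than these pairs. The number of classes above and below was 1 and 8 for FGF, 1 and 8 for Hox 5 to 9, 1 and 3 for WNT, 1 and 4 for dissociation, and 1 and 4 for the integrated stress response. It was 2 and 4 for retinoic acid, 2 and 3 for somite matrix, 2 and 2 for G2 and M phase, 2 and 1 for hypoxia, and 1 and 1 for the ZEB and SNAIL family.

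Genes of the FGF and ERK response were at 0.19 in spinal cord-like cells, where the percentile was within the range with cells averaged (97.46), and -0.33 in notochord-like cells. The WNT response was at 0.20 in clusters 2+6, within the range with classes from projection (percentile 97.2), and -0.36 in endoderm-like cells. Retinoic acid pathway genes were at 0.33 in presomitic mesoderm-like cells and -0.24 in clusters 2+6. Hox groups 5 to 9 were at 0.13 in clusters 2+6, which members of this list lead, and -1.31 in spinal cord-like cells. With classes from projection their percentile in clusters 2+6 was 9.39. The ZEB and SNAIL family was at 0.34 in presomitic mesoderm-like cells and -0.33 in cluster 0, and the percentiles fell within the range after thinning (97.04) and with a prior of 5 CPM (4.67). Somite extracellular matrix genes were at 0.26 in spinal cord-like cells and -0.15 in notochord-like cells, both within the range after thinning (percentiles 90.5 and 6.67), and the latter also with classes from projection (7.41). Genes of G2 and M phase were at 0.17 in endoderm-like cells and -0.16 in notochord-like cells. Hypoxia and glycolysis genes were at 0.18 in somite-like cells and -0.066 in clusters 2+6, where the percentile turned to 98.03 with classes from projection. The integrated stress response was at 0.23 in spinal cord-like cells and -0.19 in notochord-like cells, and the former fell inside the random range after thinning to 5000 UMIs, at a percentile of 49.5, and with cells averaged, at 95.8. Dissociation and immediate early genes were at 0.38 in neuromesodermal progenitor-like cells and -0.40 in cluster 0, the latter within the range after thinning (percentile 20.98).

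Cluster 15, which no comparison within classes used, held 40 of 6688 dTAG-13 cells, a share of 0.598%, and 2 untreated cells. Its leading genes included Krt19, Rab25, Upk1a and Krt18, its median was 93677.5 UMIs per cell, and its median doublet score 0.165.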

How the results depend on the processing

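The tests of Zeb2 and Zeb1 under each alternative, of named genes in classes without the 5 cells with most of their UMIs, of the whole-library lists without clusters 14 and 15 and of the share part under projection were chosen only after the result was seen; the other alternatives were planned. No paired analysis was possible because each group holds 1 library, and no library could be left out or regrouped. Of the list percentiles under all alternatives, 1457 kept their side of the random range, 84 moved into it, 49 moved out of it and 2 went from one side of it to the other. The counting error is here the distance from the middle of the counting interval to its end. Of the log2 ratios of named genes, Zeb2 and Zeb1, 1432 moved by less than this error, 194 by more and 2 reversed. Of the share differences, 66 moved by less than it, 22 by more and 1 with an interval clear of 0 reversed. The endothelium-like difference, whose shares had overlapping intervals, also turned, from -0.209 to 1.17 with each library clustered alone. The epithelial list in neuromesodermal progenitor-like, spinal cord-like and cluster 2+6 cells kept its side in all 7 alternatives run for classes. The whole-library epithelial, Hox 1 to 4 and Hox 5 to 9 lists kept theirs in all 9 run for the whole library. Apart from cluster 15 under projection, the cause of the shifts was not tested.

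Share differences are in percentage points, dTAG-13 minus untreated. With each library clustered alone they were 3.93 for endoderm-like, 1.17 for endothelium-like, -4.40 for epiblast-like, 2.89 for notochord-like, 2.53 for pluripotent-like and 3.24 for spinal cord-like cells. The same setting gave 10.4 for cluster 0, 30.5 for clusters 1+8, 0.927 for cluster 15 and -34.6 for clusters 2+6, which no dTAG-13 cluster matched. No untreated cluster then matched endoderm-like or spinal cord-like cells, and no dTAG-13 cluster epiblast-like cells, so these differences compare with 0. Neuromesodermal progenitor-like and cluster 2+6 cells counted together were at -31.5, and between -24.9 and -41.9 over the alternatives. Neuromesodermal progenitor-like cells were at -18.1 and clusters 2+6 at -13.8 with at least 2500 genes detected. Clustering without genes at an absolute log2 ratio of 1 or more gave -6.16 for neuromesodermal progenitor-like cells, 13.4 for clusters 1+8 and -18.7 for clusters 2+6. Clusters 1+8 and 2+6 were at 18.6 and -21.6 with 4000 highly variable genes, at 18.6 and -21.2 at resolution 2, and at 16.6 and -18.0 under projection. Projection turned cluster 15 to -0.0321, since its 2 untreated cells cannot be the most common among 15 neighbours. Notochord-like cells were at 2.77 without doublet removal.

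The log2 ratio of Zeb2 in the whole library was 0.43 with DESeq2 size factors and 0.51 with the mean over cells. Without doublet removal, with all cells clustered and named again, Zeb2 was at 0.89 in endoderm-like and 0.23 in somite-like cells. Thinned to 5000 UMIs, it was 0.60 in cluster 0 and 0.22 in clusters 1+8, and under projection 0.42 in clusters 1+8. Fgfbp1 in endoderm-like cells reversed to -0.43 when thinned. Etv2 in somite-like cells reversed to -0.41 without the 5 cells with most of its UMIs in each library. Of 160 named genes in classes, that setting moved 27 by more than the counting error and turned 1, and the ratio of 7, that 1 included, moved by over 1.5-fold. The share part of spinal cord markers reversed to 0.00899 under projection. The difference in median genes per cell was 12 at 2500 UMIs and 80 without thinning, and that of the G1 share 1.33 at 2500 UMIs.

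Values below are percentiles of lists among matched random lists. They are those that crossed a limit of the random range or the middle of it. With edgeR TMM scaling, the whole library had dermomyotome and myotome markers at 4.04. Clusters 2+6 had somite extracellular matrix and adhesion at 97.48. With DESeq2 size factors, the whole library had dermomyotome and myotome markers at 4.44 and epiblast and primitive streak markers at 97.2. Presomitic mesoderm-like cells had Hox groups 1 to 4 at 2.49. With the mean over cells of each cell's CPM, the whole library had epiblast and primitive streak markers at 88.2 and retinoic acid pathway at 2.36. Endoderm-like cells had epithelial at 95.5, Hox groups 5 to 9 at 4.27 and dissociation and immediate early at 22.8. Neuromesodermal progenitor-like cells had FGF and ERK response at 4.44. Notochord-like cells had canonical WNT response at 2.37 and p53 response at 4.16. Presomitic mesoderm-like cells had Notch and segmentation clock at 7.6 and Hox groups 1 to 4 at 2.15. Somite-like cells had FGF and ERK response at 13.1. Spinal cord-like cells had FGF and ERK response at 97.46 and integrated stress response at 95.8. Cluster 0 had BMP and SMAD response at 94.2. Clusters 1+8 had G2 and M phase at 0.14 and dissociation and immediate early at 0.6. Clusters 2+6 had Notch and segmentation clock at 57.3 and somite extracellular matrix and adhesion at 92.6. With a prior of 5 CPM, the whole library had dermomyotome and myotome markers at 4.87, neuron markers at 95.8 and neural crest markers at 94.2. It also had cardiac markers at 98.2. Endoderm-like cells had dissociation and immediate early at 4.34. Pluripotent-like cells had BMP and SMAD response at 0.79 and retinoic acid pathway at 5.29. Presomitic mesoderm-like cells had Notch and segmentation clock at 2.76, Hox groups 1 to 4 at 1.9 and dissociation and immediate early at 3.53. Cluster 0 had ZEB and SNAIL family at 4.67 and BMP and SMAD response at 90.3. Clusters 1+8 had retinoic acid pathway at 2.4. Clusters 2+6 had Notch and segmentation clock at 9.84. Without doublet removal, the whole library had retinoic acid pathway at 1.89 and dissociation and immediate early at 98.02. Endoderm-like cells had FGF and ERK response at 7.52, Hox groups 1 to 4 at 69.4 and Hox groups 5 to 9 at 100. They also had dissociation and immediate early at 2.83, mitochondrial transcripts at 1.05 and somite extracellular matrix and adhesion at 0.05. Neuromesodermal progenitor-like cells had FGF and ERK response at 29.1, S phase at 8.55 and integrated stress response at 1.85. They also had hypoxia and glycolysis at 1.65. Notochord-like cells had Hox groups 1 to 4 at 5.03 and p53 response at 13.8. Pluripotent-like cells had FGF and ERK response at 4.32 and retinoic acid pathway at 8.74. Presomitic mesoderm-like cells had Notch and segmentation clock at 5.81 and S phase at 6.18. Somite-like cells had ZEB and SNAIL family at 0.845, mesenchymal at 0 and canonical WNT response at 1.91. They also had retinoic acid pathway at 30.4, dissociation and immediate early at 62.6 and somite extracellular matrix and adhesion at 0.03. Spinal cord-like cells had canonical WNT response at 0.23 and hypoxia and glycolysis at 99.1. Cluster 0 had BMP and SMAD response at 91.2 and retinoic acid pathway at 3.26. Clusters 1+8 had retinoic acid pathway at 0.38 and integrated stress response at 1.7. Clusters 2+6 had mesenchymal at 3.28 and somite extracellular matrix and adhesion at 71.7. With each cell thinned to 5000 UMIs, the whole library had neuron markers at 84.7, endothelium markers at 2.35 and epiblast and primitive streak markers at 96.7. It also had retinoic acid pathway at 1.3 and S phase at 2.35. Endoderm-like cells had epithelial at 88.1, FGF and ERK response at 21.4 and integrated stress response at 24.04. They also had dissociation and immediate early at 80.96. Neuromesodermal progenitor-like cells had ZEB and SNAIL family at 1.43, mesenchymal at 1.57 and G2 and M phase at 1.23. They also had somite extracellular matrix and adhesion at 64.95. Notochord-like cells had canonical WNT response at 1.15 and somite extracellular matrix and adhesion at 6.67. Pluripotent-like cells had FGF and ERK response at 43.6, retinoic acid pathway at 15.7 and integrated stress response at 0.38. They also had hypoxia and glycolysis at 98.7 and dissociation and immediate early at 98.95. Presomitic mesoderm-like cells had ZEB and SNAIL family at 97.04, epithelial at 39.1 and Notch and segmentation clock at 29.05. They also had dissociation and immediate early at 87.6. Somite-like cells had Notch and segmentation clock at 3.62, FGF and ERK response at 9.28 and integrated stress response at 2.02. They also had dissociation and immediate early at 32.2. Spinal cord-like cells had retinoic acid pathway at 54.97, p53 response at 3.69 and integrated stress response at 49.5. They also had somite extracellular matrix and adhesion at 90.5. Cluster 0 had BMP and SMAD response at 97.4, Hox groups 1 to 4 at 4.97 and G2 and M phase at 98.9. It also had p53 response at 2.58, dissociation and immediate early at 20.98 and somite extracellular matrix and adhesion at 99. Clusters 1+8 had G2 and M phase at 2.38. Clusters 2+6 had mesenchymal at 57.1 and somite extracellular matrix and adhesion at 93.6. With classes from projection, neuromesodermal progenitor-like cells had mesenchymal at 0.9, Hox groups 5 to 9 at 0.15 and somite extracellular matrix and adhesion at 2.89. Notochord-like cells had Notch and segmentation clock at 2.505, canonical WNT response at 0.88 and S phase at 0.04. They also had p53 response at 11.9, dissociation and immediate early at 0.76 and somite extracellular matrix and adhesion at 7.41. Pluripotent-like cells had FGF and ERK response at 3.02. Presomitic mesoderm-like cells had mesenchymal at 1.52 and Notch and segmentation clock at 3.63. Somite-like cells had mesenchymal at 1.94 and S phase at 0.75. Clusters 1+8 had G2 and M phase at 0.42 and p53 response at 0.21. Clusters 2+6 had ZEB and SNAIL family at 1.39, canonical WNT response at 97.2 and Hox groups 5 to 9 at 9.39. They also had p53 response at 4.5, hypoxia and glycolysis at 98.03 and somite extracellular matrix and adhesion at 62.6. With no minimum on UMIs, the whole library had dermomyotome and myotome markers at 2.75 and neuron markers at 97.04. With at least 2500 genes detected per cell, the whole library had neuron markers at 96.2.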

Other observations

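The genes in this paragraph and the next were chosen after their values were seen. The histone transcripts Hist1h2ap, Hist1h2ae and Hist1h1b were lower in the dTAG-13 library in all 10 classes, whereas Hist1h1c went both ways. Hist1h2ap had log2 ratios from -0.91 in clusters 1+8 to -1.26 in presomitic mesoderm-like and endoderm-like cells. Hist1h2ae ranged from -0.49 in clusters 1+8 to -0.93 in endoderm-like cells. Hist1h1b, a linker histone transcript as is Hist1h1c, ranged from -0.17 in clusters 1+8 to -0.93 in endoderm-like cells. Hist1h1c ranged from -0.34 (95% interval -0.76 to 0.06) in spinal cord-like cells to 0.25 (0.05 to 0.46) in neuromesodermal progenitor-like cells, and stood at 41.6 CPM in both whole libraries. Histone genes belong to a family of near-identical copies, so UMIs of one copy and another are hard to assign.

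Lefty1, a secreted Nodal antagonist, went both ways. In presomitic mesoderm-like cells it stood at 5.81 CPM untreated and 19.2 CPM with dTAG-13 (log2 ratio 1.57), in neuromesodermal progenitor-like cells at 12.2 and 29.5 CPM (1.21), and in somite-like cells at 11.8 and 25.1 CPM (1.03). It was lower in spinal cord-like cells, at 54.6 and 1.79 CPM (-4.32), in clusters 2+6 at 29.4 and 7.72 CPM (-1.80), and in cluster 0 at 178 and 62.4 CPM (-1.50). Few cells held these UMIs: 104 of 148 UMIs of the untreated spinal cord-like cells came from 5 of 149 cells, 403 of 1453 in untreated clusters 2+6 from 5 of 2001, and 533 of 1089 in untreated cluster 0 from 5 of 301. Without the top 5 cells of each library, Lefty1 was at -2.68 in clusters 2+6 and -0.82 in cluster 0, and no UMI of it was left in dTAG-13 spinal cord-like cells, which held 7. Notochord-like cells held the most, at 329 and 402 CPM (0.29).

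The tests in the paragraphs that follow were chosen only after the result was seen, except that of finer clusters for Zeb2 at 20 CPM in either library; clustering without genes at an absolute log2 ratio of 1 or more was settled beforehand, but its use as a test here was not. No biological explanation was tested. The one the design names, the degradation of Zeb2, stays open as a hypothesis throughout, because it is confounded with the pool of gastruloids.

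Clusters 0 and 1+8 held larger shares and clusters 2+6 a smaller share of the dTAG-13 library. A shift of the whole library in the genes at an absolute log2 ratio of 1 or more is argued against as the whole cause. Clustering without them left differences of 15.2 points in cluster 0, 13.4 in clusters 1+8 and -18.7 in clusters 2+6. Genes with smaller ratios stayed in that clustering, so a shift in them is not covered. Its clusters were matched to classes by the cells of the first clustering. A shift of all cells in epithelial genes is argued against by pluripotent-like cells. There the list had a median of 0.047 against 1.22 in the whole library, and Epcam was at -0.0041 (95% interval -0.07 to 0.06) against 1.28. In the other 9 classes the list lay above the random range, so a shift in some classes only stays open. The 12 lowest genes had a median of -0.76 in pluripotent-like cells against -1.19, but their median level of 2.16 CPM there was too low to read them as a set. Hist1h2ap, 1 of the 12, was readable there, at 28.0 against 13.9 CPM (-0.96, 95% interval -1.26 to -0.76). A shift of all cells in this gene stays open. A difference between the 2 pools of gastruloids unrelated to dTAG-13 cannot be told apart from an effect of it, with 1 library per group.

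Epithelial genes were higher within mesodermal and neural classes of the dTAG-13 library. In neuromesodermal progenitor-like, spinal cord-like and cluster 2+6 cells, free RNA with the make-up of the whole dTAG-13 library is argued against. The genes needed at least 6.33 times the share of such RNA that pluripotency genes allow. Free RNA shed mainly by epithelial-like cells is not limited by pluripotency genes. In neuromesodermal progenitor-like cells the genes of clusters 1+8 below leave it open as well. In presomitic mesoderm-like and somite-like cells free RNA stays a candidate explanation, at no more than 0.969 times. Cells or doublets of clusters 1+8 are argued against in spinal cord-like and cluster 2+6 cells. There the upper limit of the gain of Sfn and Upk1a was 41.5% of the gain needed. Those of cluster 0 are argued against likewise by Pim2 and Pou3f1, at 10.9%, there and in neuromesodermal progenitor-like cells. That limit takes a class's own level as unchanged. In spinal cord-like cells Pim2 fell from 25.8 to 14.3 CPM and Pou3f1 from 18.1 to 14.8 CPM, which could hide a gain. Pou3f1 also fell in clusters 2+6, from 11.5 to 5.73 CPM. Even so, all Pim2 in dTAG-13 spinal cord-like cells was 14.3 CPM beside 141 CPM in cluster 0, where 29.0% of the cluster 0 level was needed. Cells of clusters 1+8 cannot be told apart from a difference within cells in neuromesodermal progenitor-like cells (81.5%) or in presomitic mesoderm-like and somite-like cells (249%): in the former the 2 genes disagree, as the gain of their cluster 1+8 level was 4.58% for Sfn (upper limit 6.31%) and 14.7% for Upk1a (upper limit 19.1%) with 23.4% needed, and in somite-like cells Upk1a gained 2.33% with 1.51% needed and Sfn 0.755%. Cells or doublets of the notochord-like and endoderm-like clusters were not tested as a source and stay open. These clusters also held Krt8 (396 and 624 CPM) and Epcam (516 and 752 CPM). A difference between the pools stays open here too.

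Zeb2 transcript was higher within 8 classes of the dTAG-13 library. Scaling is argued against, since the lowest ratio under TMM or DESeq2 among these classes was 0.37. Free RNA is argued against by pluripotent-like cells of the dTAG-13 library, whose upper limit was 3.09 CPM, against a smallest gain of 21.8 CPM in the classes above. A different mix of finer clusters is argued against. Zeb2 was higher in 19 of 19 finer clusters with at least 20 CPM in either library (log2 ratios 0.27 to 1.55). It was higher in 17 of 17 with that level in the untreated library (0.27 to 1.03). With no minimum it was higher in 21 of 22 (-0.16 to 1.55), but its interval lay above 0 in only 19. The others, mainly of endoderm-like or pluripotent-like cells, had intervals that held 0. A response of the transcript to the loss of its protein is a hypothesis that was not tested, and a difference between the pools stays open.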
